A study of Mus musculus with 8 samples.

How the data were processed

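BRD4, a bromodomain protein that binds acetylated histones, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts (MEFs) at 0, 8, 16 and 20 h, with 1 library per time point. Peak lists of the 4 BRD4 libraries were analysed. The 4 input libraries of the same time points were not analysed here. Per the labels' protocols, the MEFs came from Brd4-floxed mice with a tamoxifen-inducible Cre, chromatin was fixed with formaldehyde and sonicated, an antibody to BRD4 made by the submitters was used, and libraries were sequenced as single-end reads. The protocols describe how Brd4 can be deleted with 4-hydroxytamoxifen, and no label says that any of these libraries came from treated cells. How the cells were brought to each stage of the cell cycle is not given in the sources used here.

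Per the submitters' processing notes, Bowtie2 2.3.4.1, MACS2 2.1.1.20160309 and deepTools were used with the mouse build mm10. The deposited lists are in the broad peak format that MACS2 writes, with 1 list per library. The fold enrichment of each peak is the authors' value, a linear ratio over the local background that the peak caller gives. The p and q of each peak are the authors' values on a −log10 scale. The integer score that the authors deposited in the fifth column was not used. The settings and the control passed to MACS2 are not given in the sources used here. The smallest −log10 q was 1.08, 1.01, 1.00 and 1.03 in the lists of 0, 8, 16 and 20 h. These values were used to describe, rank and filter peaks within a list, and are not read as a change in occupancy between lists. The median fold enrichment at equal −log10 p was set side by side between lists once, as a check of sensitivity.

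The lists hold no read numbers, so the depth of each library is unknown. A list of more peaks can come from a deeper library or a stronger enrichment, and this affects every count compared between time points. Intervals are exact Clopper-Pearson intervals at 95% over peaks. They cover counting error among the peaks of 1 list only, and say nothing about the spread between cultures. With 1 library per time point there is no replicate error, so no test of a difference between time points was made. The p-values of the closing section are for 2 correlations across chromosomes, added after seeing the data, and describe these libraries only.

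Peaks on chromosomes 1 to 19, X and Y were used. Coordinates are 1-based mm10 positions. Genes were the 21887 protein-coding genes of the RefSeq table of assembly GRCm38.p6, the same primary build as mm10. That table gives the start and end of each gene without strand or single transcripts. The planned class of peaks within 1 kb of a transcript start was therefore replaced by peaks within 1 kb of either end of a gene, called gene-end peaks, so that the 3-prime end counts as well as the promoter. A gene was called at a time point when it had a gene-end peak in that list. A gene that was not called could still have a peak elsewhere inside it, which is given for some genes only. Other peaks were classed as elsewhere in a gene or outside genes. A peak near several genes counted for each of them.

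Peaks of different lists were shared when they overlapped by at least 1 bp. Chance overlap and location were described with 100 random placements of the peaks on their own chromosomes, drawn with NumPy. Each placement lay between the first and the last protein-coding gene or peak of the chromosome. Regions were made by merging overlapping peaks of the 4 lists. For each of 19 gene lists, the number of called members was set beside 10000 random lists of protein-coding genes of the same size, without matching on CpG content since no genome sequence was used. These percentages describe each library and are not p-values between time points. Added after seeing the data, the called members were also set beside random lists drawn from the 7666 genes called in at least 1 list, each as long as the number of members called in at least 1 list. Both sides are then chosen by being called, so this shows how calls divide over the time points and is no test of whether a list is called more often than other genes. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The overlap and gene calls were tested on simulated data: 1200 of 1200 planted overlaps among 3000 simulated 16 h peaks and 200 of 200 genes given a peak were recovered, and 21 of 21 counts equalled those of bedtools.

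The gene lists and the rule for named genes were fixed before the data were examined. The rule always names 17 genes: Fos, Myc, Ccnd1, Ccne1, E2f1, Cdc6, Mcm2, Pcna, Ccna2, Ccnb1, Cdk1, Plk1, Aurka, Aurkb, Cdkn1a, Col1a1 and Brd4. It adds the 10 genes with the highest −log10 q that were called at a later time and had no peak within 5 kb of a gene end at 0 h, and 10 the other way round. For 16 h against 8 h and 20 h against 16 h it takes 5 genes each way. It adds the 5 genes with the highest −log10 q in each list and, per gene list, up to 4 members called later and not at 0 h and up to 4 called at all 4 times. Predicted genes are left out, and some genes that the rule takes are not named in the Results. Genes named outside the rule are marked as chosen after their values were seen. Alternatives were a −log10 q of at least 3, a fold enrichment of at least 4, the strongest 4481 peaks of each list (the length of the shortest), a shared length of at least 50% of the shorter peak, a 3 kb window, the whole gene with 1 kb on both sides, all sequences in the files, and peaks within 1 kb joined. Leaving out chromosomes 4, 6 and 13 and leaving out the 20 h list were added after seeing the data.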

Results

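BRD4 occupancy was profiled by ChIP-seq in MEFs at 0, 8, 16 and 20 h to follow it through the stages of the cell cycle. Each time point was represented by 1 BRD4 library, so none of the differences below has a replicate check. The lists held 4481 peaks at 0 h, 9701 at 8 h, 12661 at 16 h and 9731 at 20 h on chromosomes 1 to 19, X and Y. They covered 1.96, 4.47, 6.11 and 5.79 Mb, and the median peak width was 360, 371, 378 and 431 bp. With a fold enrichment of at least 4 the lists held 2391, 1712, 1544 and 1853 peaks, so the order of the time points depended on the cut-off. Sequencing depth is unknown for these lists. The deposited list of 20 h is named in another style than those of 0, 8 and 16 h, and it repeats the run sample index of the 0 h list where the other 3 lists have consecutive ones. If these names mark another batch, it cannot be told apart from time, because the 20 h time point has no other library.

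To ask how far occupied regions were shared along the time course, the lists were overlapped. Of the 0 h peaks, 69.9% (95% Clopper-Pearson interval 68.5 to 71.2%) overlapped an 8 h peak and 77.8% (76.5 to 79.0%) a 16 h peak. These shares depended on the peaks used: they were 50.4 and 51.4% among the strongest 4481 peaks of each list, and 29.9 and 29.6% among peaks with a fold enrichment of at least 4. Of the 8 h peaks, 59.0% (58.1 to 60.0%) overlapped a 16 h peak. The 20 h list shared less, with 29.3% (28.4 to 30.2%) of its peaks in the 16 h list. Of the 20 h peaks, 10.9% (10.3 to 11.5%) lay in the 0 h list. The shares of 8 and 16 h peaks in that short list were 32.0 and 27.0%. With a fold enrichment of at least 4, 37.1% of the 8 h peaks and 10.5% of the 20 h peaks overlapped a 16 h peak. Randomly placed peaks overlapped at no more than 0.848% in any pair. The placements did not keep the share of peaks at gene ends. They therefore understate the overlap that a common preference for gene ends would give. The 4 lists merged into 23277 regions, of which 901 were occupied at all 4 times, 1913 at 0, 8 and 16 h without 20 h, and 6330 at 20 h alone. Among the genes with a gene-end peak at every time were Zfp532, a zinc finger gene, with a fold enrichment of 8.74, 8.57, 7.56 and 4.20 at 0, 8, 16 and 20 h, and Brd2, a BET family paralog of Brd4, whose peak is shared with H2-DMa, with 6.08 at 0 h, 6.93 at 16 h and 4.08 at 20 h. Tbl1xr1, Snx9 and Pcif1 ranked next after Zfp532 by −log10 q among gene-end peaks at 0 h and were also called at all 4 times.

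Gene ends held most BRD4 peaks at 0 h and few at 20 h. Gene-end peaks made up 63.2% of the list at 0 h (61.8 to 64.6%), 51.0% at 8 h (50.0 to 52.0%), 45.2% at 16 h (44.3 to 46.1%) and 16.0% at 20 h (15.3 to 16.7%), against a mean of 3.84 to 3.92% after random placement. Peaks outside genes made up 15.5, 21.3, 27.5 and 48.1% at 0, 8, 16 and 20 h, and peaks elsewhere in a gene 21.3, 27.7, 27.3 and 35.9%. Among the strongest 4481 peaks of each list the gene-end share was 62.1% at 8 h, 58.4% at 16 h and 14.5% at 20 h. The gap between 16 and 20 h was thus present in lists of equal length, and that between 0 and 16 h was smaller in them.

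**Figure D1:**
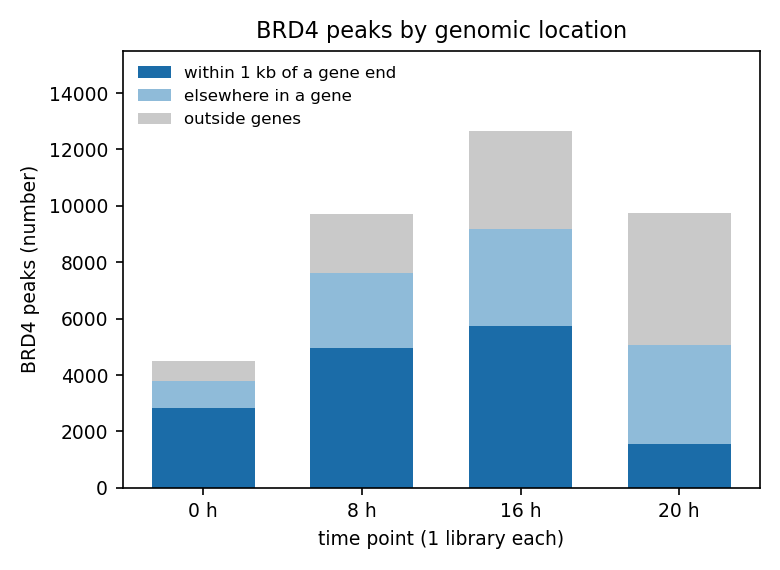
Number of BRD4 peaks (y axis) in the list of each time point (x axis, 1 library each), stacked by location: within 1 kb of a protein-coding gene's end, elsewhere in a gene, or outside genes. Gene-end peaks numbered 2833, 4943, 5725 and 1555 at 0, 8, 16 and 20 h, and peaks outside genes 694, 2071, 3478 and 4679.

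At the level of genes, 3139 of 21887 protein-coding genes had a gene-end peak at 0 h, 5345 at 8 h, 6030 at 16 h and 1611 at 20 h. Against 0 h, 2717 genes were called at 8 h and not at 0 h and 511 the other way round, and 3300 were called at 16 h and not at 0 h with 409 the other way. At 20 h, 862 genes were called that were not called at 0 h, and 2390 the other way. From 8 to 16 h, 1865 genes were called at 16 h alone of the pair and 1180 at 8 h alone, and from 16 to 20 h the numbers were 367 at 20 h alone and 4786 at 16 h alone. The excess at 8 and 16 h depended on list length: among the strongest 4481 peaks of each list, 3141 genes were called at 8 h, 2954 at 16 h and 719 at 20 h. With a fold enrichment of at least 4 the order turned, with 1696 genes at 0 h, 1308 at 8 h, 1028 at 16 h and 148 at 20 h. That cut-off kept 2391 of 4481 peaks at 0 h and 1544 of 12661 at 16 h. It is thus not equally strict in the lists, and the turned order is not read as a change in occupancy.

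The genes with the strongest peaks at 8 h and none within 5 kb at 0 h were the zinc finger gene Zfp869 (fold enrichment 5.87 at 8 h), the RNA helicase gene Dhx15 (5.72), the ribosomal protein genes Rpl27a (6.16) and Rps23 (4.59), Abce1, a ribosome recycling factor, whose peak is shared with the anaphase-promoting complex gene Anapc10 (5.09), Cyb5d2 with its neighbour Zzef1 (5.49), Synj2 (5.65) and Nap1l1, a nucleosome assembly gene (5.05). All of these except Synj2 were also called at 16 h. In the other direction, Ptx3, Vangl2, Slc25a24, Trdmt1, Tmem94, Ankrd34a with Lix1l, Tmem170b, Eya1 and Fam120b were called at 0 h and not at 8 h, and of these Ptx3, Vangl2, Trdmt1, Eya1 and Fam120b were called again at 16 h. At 16 h the strongest genes without a peak at 0 h were Atp5g2, a subunit gene of the mitochondrial ATP synthase (fold enrichment 5.21), Cdk1, the kinase that drives entry into mitosis (5.22), the linker histone gene H1f3 (5.39), the chromatin remodeller Chd1 (5.13), the elongation factor Eef2 (4.45), Chchd4 with Tmem43 (4.50), the collagen gene Col3a1 (5.73) and Abce1 with Anapc10 (4.19). Iba57, Mrln, Slc25a24, the Mediator subunit gene Med17, Tmem94, Nck1, Ankrd34a with Lix1l, Tmem170b and Pex7 were called at 0 h and not at 16 h.

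Genes for the G1/S transition and DNA replication were called more often at 8 and 16 h than at 0 h. Of 53 members, 7 had a gene-end peak at 0 h, 24 at 8 h, 30 at 16 h and 10 at 20 h. Random lists of all protein-coding genes had medians of 7.5, 13, 15 and 4. E2f1, a transcription factor that drives entry into S phase (chromosome 2, 154559400 to 154569892), was called at 8 h (fold enrichment 4.42, −log10 q 5.5) and 16 h (4.00 and 4.6). Ccne1, which encodes cyclin E1 (chromosome 7, 38097984 to 38107490), was called at the same times (2.98 and 3.36-fold). Usp1 and Rrm2, a subunit gene of ribonucleotide reductase, were called at 8, 16 and 20 h, and E2f3 at 16 and 20 h. At 0 and 8 h E2f3 had a peak inside the gene. Cdk4 and the replication licensing gene Cdt1 were called at all 4 times. Pcna, the replication clamp, was called at 16 h with a peak shared with Cds2 (3.01-fold), and Ccnd1, Cdc6 and Mcm2 had no peak at any time. Among the strongest 4481 peaks of each list, 7, 10, 20 and 4 members were called at 0, 8, 16 and 20 h.

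G2/M and mitosis genes were called most often at 16 h, the time with the most called genes of any kind. Of 66 members, 6 had a gene-end peak at 0 h, 21 at 8 h, 48 at 16 h and 22 at 20 h, against random medians of 9, 16, 18 and 5. At 16 h the 48 genes rested on 48 separate peaks. Cdk1 (chromosome 10, 69335146 to 69352912) was not called at 0 h and had a fold enrichment of 3.06 at 8 h, 5.22 at 16 h and 3.92 at 20 h, with a −log10 q of 1.6, 10.8 and 7.1 within the respective lists. Incenp, a subunit gene of the chromosomal passenger complex, was called at 8, 16 and 20 h, with its strongest gene-end peak at another end at 8 h than at 16 and 20 h. The condensin gene Smc4, whose peak is shared with Ift80, was called at the same times. Foxm1, a transcription factor of mitotic genes, was called at 8 and 16 h with a peak shared with Rhno1 (4.35-fold at 16 h). Aurkb, a mitotic kinase gene, was called at 16 and 20 h (3.04 and 3.28-fold). Aurka, with a peak shared with Cstf1, Ndc80 with Spdya and Cks2 were called at all 4 times. The strongest gene-end peak of Cks2 lay beyond one end at 0 and 8 h, shared with Secisbp2, and at the opposite end at 16 and 20 h. Ccnb1 and Plk1 had no peak in any list, and Ccna2 had a peak inside the gene at 16 h and none at its ends. Among the strongest 4481 peaks of each list the counts were 6, 11, 31 and 8, which keeps the highest count at 16 h. Called genes of any kind then numbered 3139, 3141, 2954 and 719. The lower G2/M count at 20 h thus went along with fewer called genes of any kind, while the higher count at 16 h than at 0 and 8 h did not follow their number.

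**Figure D2:**
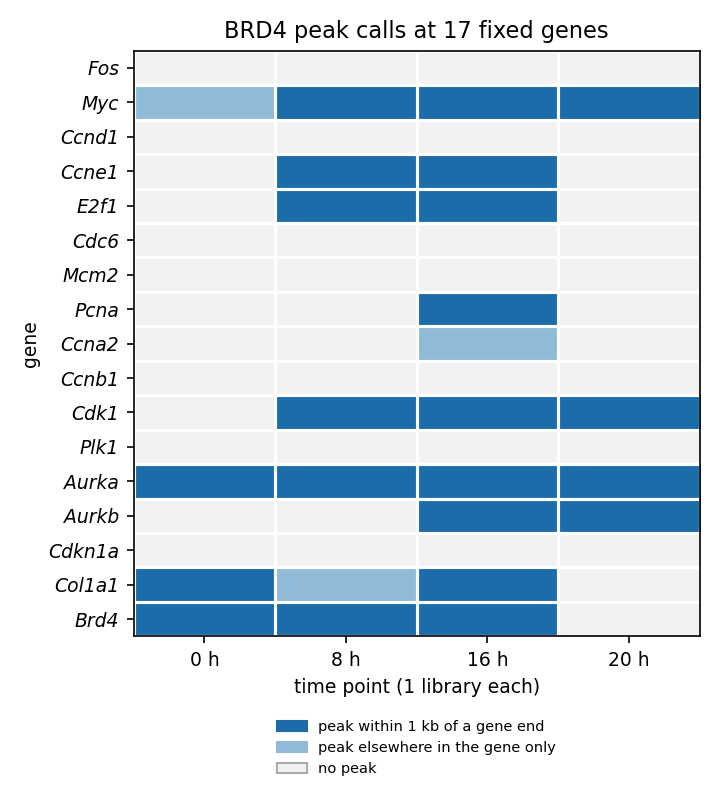
Peak calls at the 17 genes fixed in advance (rows) at each time point (columns, 1 library each). Dark tiles mark a peak within 1 kb of a gene end, light tiles a peak elsewhere in the gene alone, and pale tiles no peak; Ccne1 and E2f1 were called at 8 and 16 h, Cdk1 at 8, 16 and 20 h, and Aurkb at 16 and 20 h.

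Replication-dependent histone genes, which supply histones during DNA synthesis, were called late in the series. Of 63 members, 1 had a gene-end peak at 0 h, 7 at 8 h, 40 at 16 h and 52 at 20 h, against random medians of 9, 15, 17 and 4. The 40 genes at 16 h rested on 29 separate peaks and the 52 at 20 h on 35, since neighbouring histone genes share peaks. H1f3 (chromosome 13, 23555032 to 23555807) was called at 16 h (fold enrichment 5.39) and 20 h (4.10), as were H1f2 (4.18 and 3.56) and the pair H2bc18 and H3c13 on chromosome 3, which share a peak (5.25 and 3.43). H4c14 was called at all 4 times. Of the 53 members on chromosome 13, 31 were called at 16 h and 44 at 20 h, and of the 10 on other chromosomes 9 and 8. Histone genes are near-identical copies, and how reads that fit several copies were placed is not given in the sources used here.

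**Figure D3:**
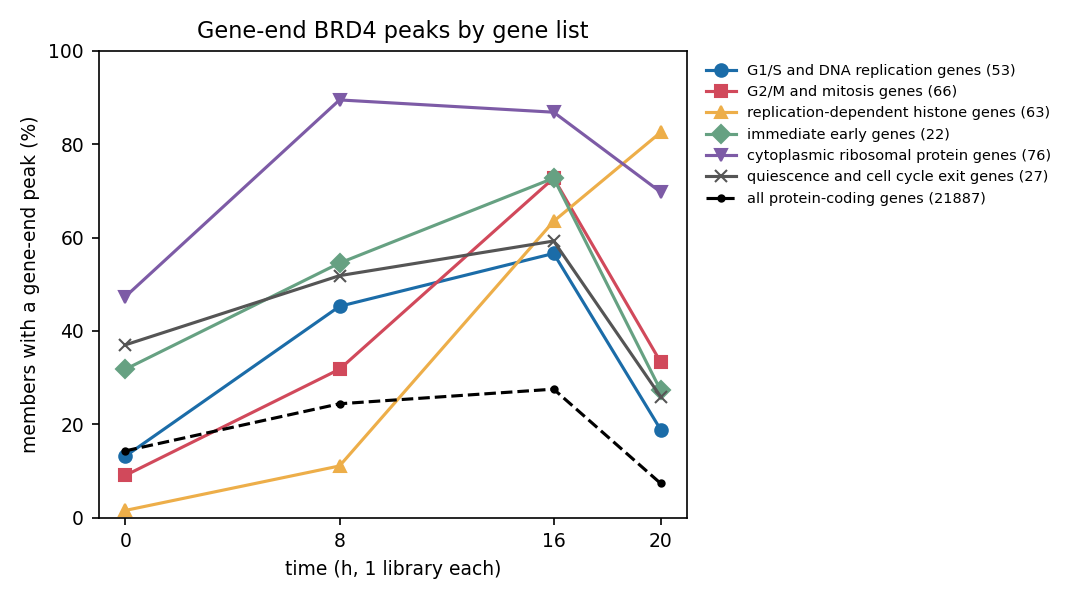
Percent of the members of 6 gene lists, and of all protein-coding genes, with a gene-end peak (y axis) against time in h (x axis, 1 library each; members in brackets). G2/M and mitosis genes went from 9.09% at 0 h to 72.7% at 16 h and 33.3% at 20 h, and histone genes from 1.59% at 0 h to 82.5% at 20 h.

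Immediate early genes, which respond first to growth signals, and growth-arrest genes were called at each time more often than random lists of all protein-coding genes in over 97% of draws. This was not particular to them. The same held for the housekeeping, cytoplasmic ribosomal protein, SRF and YAP target, and BET and transcription elongation genes described below. Immediate early genes came nearest to that limit, with 97.1% at 0 h. Fibroblast and extracellular matrix genes fell just short of it at 0 h, with 96.9%, and were above it at the later times. Of 22 immediate early genes, 7, 12, 16 and 6 were called at 0, 8, 16 and 20 h. Myc was called at 8, 16 and 20 h (fold enrichment 3.71, 2.80 and 3.04) and had a peak inside the gene at 0 h. Junb and Ier3 were called at 8 and 16 h and Fosl1 at 16 and 20 h, while Klf6, Zfp36 and Jun were called at all 4 times and Fos at none. Fosl1 had a peak inside the gene at 8 h. The strongest gene-end peak of Zfp36 lay at one end at 0 and 16 h and at the other at 8 and 20 h. Of 27 genes of quiescence and cell cycle exit, 10, 14, 16 and 7 were called. Gas1, a growth-arrest gene, Rbl1, Ccng2 and Cdkn2a were called at all 4 times, Cdkn2c at 8, 16 and 20 h, Foxo1, Foxo3 and Rb1 at 8 and 16 h, and Cdkn1a at none. At 20 h Foxo3 and Rb1 had a peak inside the gene.

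Cytoplasmic ribosomal protein genes were the list with the highest share of called members at 8 and 16 h, with 36, 68, 66 and 53 of 76 members at 0, 8, 16 and 20 h. Rpl13 had the highest −log10 q of any gene-end peak at 16 h (fold enrichment 7.95), and Rps8, Rpl5 and Rps6 were called at every time. Rps27a, Rps23 and Rps26 were called at 8, 16 and 20 h and Rpl23 at 8 and 16 h. Of 20 genes of BET proteins and transcription elongation, 10, 13, 14 and 5 were called. Brd4 itself was called at 0, 8 and 16 h (5.02, 4.06 and 4.25-fold) and not at 20 h, Hexim1 at 8, 16 and 20 h, Ccnt2 at 8 and 16 h, Larp7 and Med13 at 16 h, and Supt5 at all 4 times. Of 30 DNA damage repair genes, 3, 13, 15 and 7 were called, including Nbn and Brca2 at all 4 times and Mdc1 and Rad18 at 16 and 20 h.

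Fibroblast and extracellular matrix genes were called for 10, 22, 23 and 9 of 37 members at 0, 8, 16 and 20 h. Thbs1, Vim and Fn1 were called at all 4 times, S100a4 at 8, 16 and 20 h, Serpine1 at 8 and 16 h, Col3a1 and Timp3 at 16 h, and Col1a1, the main fibrillar collagen gene, at 0 and 16 h. At 8 h Col1a1 had a peak inside the gene, the widest of that list (4939 bp, 4.31-fold). Of 18 target genes of the factors SRF and YAP, 7, 14, 15 and 9 were called, among them Actg1, Lats2, Myh9 and Ccn2 at every time and Actb, Zyx and Tead1 at 8, 16 and 20 h. Actb had a peak inside the gene at 0 h. Housekeeping genes were called for 6, 8, 11 and 7 of 16 members and cholesterol synthesis genes for 1, 5, 8 and 1 of 18.

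Lists of other cell types had few calls. None of the 10 members each of the muscle, pluripotency and hepatocyte lists was called at any time. Calls numbered 1, 0, 1 and 0 of 15 haematopoietic markers, 0, 0, 1 and 0 of 11 epithelial markers, 1, 1, 2 and 1 of 12 neuronal markers and 0, 1, 0 and 0 of 10 endothelial markers at 0, 8, 16 and 20 h. The genes behind these were Spi1 and Map2 at 0 and 16 h, both named after their values were seen, Epcam at 16 h, Dlx2 at 8, 16 and 20 h and Erg at 8 h.

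Of the 5 genes with the highest −log10 q at 20 h, Fmo4, Cp and Tlr4 were not called at 0 h, while Pcbp1 (−log10 q 19.9, fold enrichment 6.88 at 20 h) and Wdr34 (14.1 and 5.53) were called at all 4 times. Fmo4, a flavin monooxygenase gene (chromosome 1, 162793188 to 162816072), had the highest −log10 q of any gene-end peak at 20 h (27.2, fold enrichment 9.30). It was also called at 8 h (3.76-fold) and not at 0 or 16 h. Cp, which encodes ceruloplasmin, had a fold enrichment of 7.28 at 20 h and 2.77 at 16 h, and the innate immune receptor gene Tlr4 6.68 at 20 h, with calls at 8 and 16 h too. Hebp1, Slc7a12, Ank2, Vmp1, Susd1, Col1a2 and Rps23 completed the 10 strongest genes called at 20 h and free of a peak at 0 h. Called at 0 h and not at 20 h were Ncoa6 (7.68-fold at 0 h), Fbxo4 (7.05), Lemd2 (6.87), Micu2, Ap1g1 (6.00), the histone acetyltransferase gene Kat6a (6.04), Srsf6 (6.28), Prrc2a (5.24), Arcn1 (6.51) and Ngly1 with Oxsm (6.71), and all of these genes were called at 8 and 16 h too. At 20 h Kat6a had a peak inside the gene. Between 16 and 20 h, Eif4g1, Ankrd40, Zfp236, Cpsf7 with Sdhaf2 and Ngly1 with Oxsm led the genes called at 16 h alone of the pair, and Fmo4, Hebp1, Ank2, Wdr59 and Magea10 those called at 20 h alone.

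The 20 h peaks were also spread differently over the chromosomes. Chromosomes 4, 6 and 13 held 4.59, 3.13 and 4.68% of the 16 h peaks and 9.91, 8.84 and 9.21% of the 20 h peaks, while chromosome 8 held 9.52% at 16 h and 4.74% at 20 h. The 8 h shares of chromosomes 4, 6, 8 and 13 were 4.42, 3.06, 9.86 and 3.46%. Without chromosomes 4, 6 and 13 the 20 h list still had 15.8% of its peaks at gene ends.

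**Figure D4:**
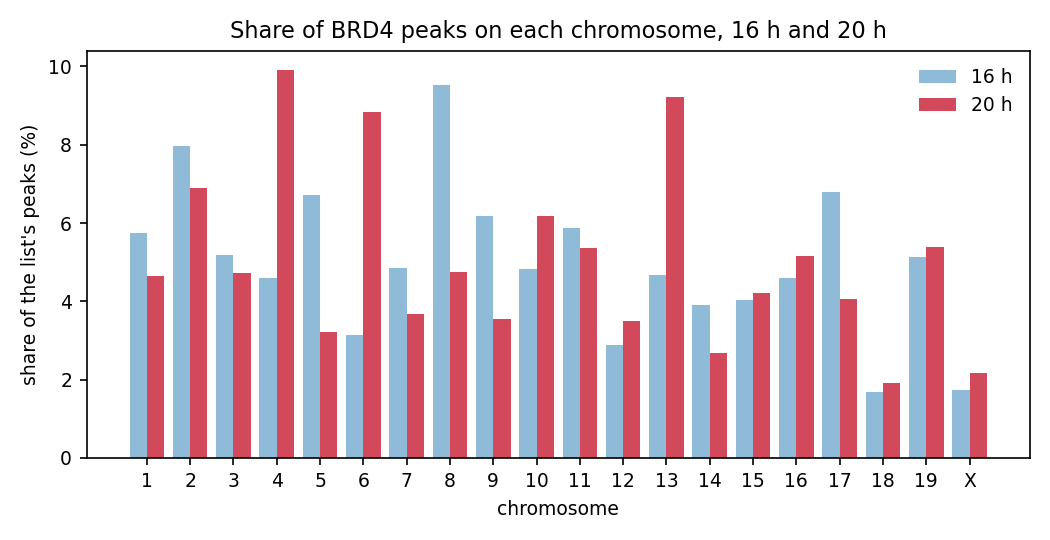
Percent of the peaks of the 16 h list and of the 20 h list (y axis, 1 library each) that lie on each chromosome (x axis). Chromosome 6 went from 3.13% at 16 h to 8.84% at 20 h and chromosome 8 from 9.52 to 4.74%.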

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

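Signal was also present outside the chromosomes used for the comparisons: 22 peaks at 0 h, 38 at 8 h, 32 at 16 h and 11 at 20 h lay on unplaced or random sequences of the build. These numbers are above the limit of 3 used for flagging, which is no test of where peaks should lie. No explanation of these peaks was tested. Adding them changed none of the 4 numbers of peaks by over 1.5 times, which so few peaks could not do in any case.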

How the results depend on the processing

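Leaving out chromosomes 4, 6 and 13, leaving out the 20 h list and drawing random lists from called genes were chosen after seeing the data. The results compared between settings here are counts or shares without a test, so none could gain or lose significance, and stricter filters lower counts by construction; other causes were not tested. No paired analysis was possible because each time point has 1 library. The alternative of the 5-prime-most transcript start was not run, since the gene table has no strand. Depth limits every count, since read numbers are unknown. The gene-end share stayed lowest at 20 h in each setting tried, and G2/M genes were called more often at 16 h than at 0 or 8 h in each setting tried for them. Of the values of other lists, 68 moved lower and 14 higher over all settings. These include 7 random-list percentages of the G1/S, G2/M and histone genes, which are not counts of other lists. For named genes the value was the number of lists that called the gene. Of these values, 92 moved lower and 4 higher, while 396 stayed within 1.5 times, of which 40 were lower and 8 higher. The fold enrichments of named genes and the times at which they were called were not compared between settings. Random lists drawn from called genes were as long as the number of members called in at least 1 list, 52 for G2/M, 36 for G1/S and 53 for histone genes. At 0, 8, 16 and 20 h, G2/M genes had 6, 21, 48 and 22 called members against medians of 21, 36, 41 and 11, G1/S genes 7, 24, 30 and 10 against 15, 25, 28 and 7, and histone genes 1, 7, 40 and 52 against 22, 37, 42 and 11. Since members and random genes were both chosen by being called, these values show how calls divide over the time points and do not test an excess over other genes. With a −log10 q of at least 3 the lists held 1586, 3034, 3909 and 3854 peaks at 0, 8, 16 and 20 h. Genes called numbered 1130, 2265, 2608 and 595. Genes called later and not at 0 h numbered 1509, 1829 and 426 at 8, 16 and 20 h, and 961 were called at 0 h and not at 20 h. The gene-end share was 65.1, 58.9 and 13.8% at 8, 16 and 20 h. The shares of 0 h peaks in the 8, 16 and 20 h lists were 58.0, 65.7 and 18.5%, and that of 20 h peaks in the 16 h list 22.6%. Regions in all lists numbered 211, in 0, 8 and 16 h 763 and in 20 h alone 2784, against 901, 2814 and 6330 as deposited. Here and below, regions in 0, 8 and 16 h are counted with or without 20 h. G1/S genes called numbered 2, 9, 17 and 4, G2/M genes 1, 6, 24 and 7, and histone genes at 8 h 0. With a fold enrichment of at least 4, peaks numbered 2391, 1712, 1544 and 1853 and genes 1696, 1308, 1028 and 148, which turned the order of 0, 8 and 16 h. This cut-off is not equally strict in the lists. Genes called later and not at 0 h numbered 686, 517 and 101, and the other way 1074 against 8 h and 1185 against 16 h. Shares of 0 h peaks in the 8, 16 and 20 h lists were 29.9, 29.6 and 5.56%, of 8 h peaks in the 16 h list 37.1% and of 20 h peaks in the 16 h list 10.5%. Regions numbered 50 in all lists, 400 in 0, 8 and 16 h and 1545 in 20 h alone. With the strongest peaks in lists of equal length, genes numbered 3141, 2954 and 719 at 8, 16 and 20 h. Those called later and not at 0 h numbered 1206, 1161 and 364, and the other way 1204 against 8 h and 1346 against 16 h, so the excess of genes at 8 and 16 h over 0 h was not kept. The gene-end share was 62.1, 58.4 and 14.5%. Shares of 0 h peaks in the 8, 16 and 20 h lists were 50.4, 51.4 and 13.5%, of 8 h peaks in the 16 h list 53.7% and of 20 h peaks in the 16 h list 23.0%. Regions numbered 386, 1632 and 3103 in the same order. G1/S genes numbered 10 at 8 h and 4 at 20 h, G2/M genes 11, 31 and 8, and histone genes 0 at 8 h. With 50% of the shorter peak shared, 65.9, 74.0 and 20.5% of 0 h peaks were in the 8, 16 and 20 h lists, 55.5% of 8 h peaks and 25.9% of 20 h peaks in the 16 h list. Joining peaks within 1 kb gave 31.4% for 20 h peaks in the 16 h list. The 3 kb window gave gene-end shares of 71.4, 58.8, 52.6 and 21.7%. With the whole gene, 3015 genes were called at 20 h and 1660 at 20 h and not at 0 h. Without chromosomes 4, 6 and 13, histone genes numbered 4, 9 and 8 at 8, 16 and 20 h, since most lie on chromosome 13, so their count was then no longer higher at 20 h than at 16 h. The share of 0 h peaks in the 20 h list was 22.0% and of 20 h peaks in the 16 h list 32.6%. Without the 20 h list, 2812 regions were in all lists used.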

Other observations

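All tests and values in this part were chosen after the results they concern had been seen. When peaks of a list within 12.5 kb of each other were joined into domains, the domain with the longest covered length was another at 16 h than at 20 h. At 8 and 16 h it spanned Amotl2, a YAP target gene, on chromosome 9 (102717149 to 102784789 at 16 h), with 10 peaks over 6030 bp at 0 h, 20 peaks over 17305 bp at 8 h, 29 peaks over 23868 bp at 16 h and 5 peaks over 3413 bp at 20 h. The 8 h domains next in length lay at Col1a1 (9332 bp), Serpine1 (7010 bp), Snai1 (6521 bp), Cep63 with Anapc13 (6487 bp) and Mroh2a with Hjurp (6258 bp). At 20 h the longest domain lay between Hmga2 and Msrb3 on chromosome 10 (120602984 to 120671798), with 15 peaks over 23566 bp, against none at 0 h, 1593 bp at 8 h and 909 bp at 16 h. The next at 20 h overlapped Tubd1 and lay in part over the neighbouring Vmp1 on chromosome 11 (86569917 to 86629435), with 19 peaks over 20008 bp, against 227, 2938 and 8131 bp at 0, 8 and 16 h. The widest peak of any list, 12552 bp with a fold enrichment of 5.05, lay over the long noncoding RNA gene Mir100hg on chromosome 9 at 20 h (41577184 to 41589735). A histone cluster on chromosome 13 (23530219 to 23586976) was the fifth domain at 20 h, with 16 peaks over 15148 bp, against 12 peaks over 6839 bp at 16 h, 1 peak of 270 bp at 8 h and none at 0 h.

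Gene-end peaks lay more often outside the gene at 20 h. Among the 1244 genes called at both 16 and 20 h, the midpoint of the strongest gene-end peak lay outside the gene in 29.6% at 16 h and 48.6% at 20 h. It lay farther outside at 20 h than at 16 h in 60.7% of these genes, and its median position moved from 172 to 18.5 bp inside the gene end. Among the 4165 genes called at both 8 and 16 h it lay outside in 24.5 and 23.6%. The peak with the highest −log10 q at 0 h (17.8) had a fold enrichment of 2.11 and lay over Rn18s-rs5, annotated as a pseudogene, on chromosome 17 (39843008 to 39847219). Peaks lay there at 8 and 16 h too and none at 20 h. Every list held peaks of low fold enrichment and high −log10 q. Peaks below 2.5-fold with a −log10 q of at least 5 numbered 9, 21, 17 and 19 at 0, 8, 16 and 20 h on all sequences. Among them at 20 h was a peak on chromosome 2 (98662230 to 98662980) with a −log10 q of 33.4 and 2.06-fold enrichment. No explanation was tested for the positions of gene-end peaks or for these low-fold peaks.

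The 20 h list differed from the others in its share of gene ends and its overlap. Weak peaks near the calling threshold are argued against as the whole cause, since 54.0% of the strongest 10% of the 20 h peaks (50.8 to 57.2%) overlapped a 16 h peak, against 94.5% of the strongest 10% at 8 h. Extra peaks on chromosomes 4, 6 and 13 are argued against as the cause of the low gene-end share, which was 15.8% without them. For the chromosome shares, cells with other chromosome copy numbers at 20 h are a candidate explanation: across the 20 chromosomes with peaks, the log2 change in share from 16 to 20 h at gene ends was correlated with that outside genes (Pearson r = 0.642, permutation p = 0.00243; Spearman rho = 0.650, permutation p = 0.00254; r = 0.588 without the 2 chromosomes farthest from the median; Benjamini-Hochberg adjusted p = 0.00303 over 2 correlations), but the far smaller changes between 8 and 16 h gave a similar r of 0.631 (permutation p = 0.00303; rho = 0.750, permutation p = 0.00023; r = 0.612 without the 2 farthest), so r alone is not specific, and on chromosome 4 the part beyond 110 Mb held 15.7% of its peaks at 20 h against 47.0% at 16 h. If the 20 h library came from another run or culture, as its naming leaves possible, that and the stage of the cell cycle cannot be told apart, because 20 h has no other library.

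More genes were called at 8 and 16 h than at 0 h. A lower sensitivity of the 0 h library may account for part of this: among peaks with a −log10 p of 5.5 to 6.5 the median fold enrichment was 4.06 at 0 h and 3.62 at 8 h, a ratio of 1.12. A loss that falls on all genes alike is argued against for the G2/M genes called at 16 h: of the 48 called at 16 h, 6 were also called at 0 h, against 17 to 30 (the middle 95%, median 24) among random genes with 16 h peaks of matched −log10 q. Below their ranges too were G1/S genes, with 7 of 30 against 9 to 19, histone genes, with 1 of 40 against 17 to 28, and DNA damage repair genes, with 3 of 15 against 4 to 11. The 40 histone genes rest on 29 separate peaks. Random genes were drawn one by one, so every range given here for histone genes is too narrow. At the lower edge were fibroblast and extracellular matrix genes, with 8 of 23 against 8 to 16, and SRF and YAP targets, with 7 of 15 against 7 to 13. The other 5 of the 11 lists compared at 16 h lay inside their ranges, among them immediate early genes with 7 of 16 against 4 to 11. Among genes called at 8 h, such a loss is argued against for the cytoplasmic ribosomal protein genes, of which 35 of 68 were also called at 0 h against 41 to 55, whereas of those called at 16 h it was 35 of 66 against 33 to 47. DNA damage repair genes had 3 of 13 against 4 to 10. Fewer peaks called at 0 h for all genes alike stays open for the G2/M genes called at 8 h, with 5 of 21 also called at 0 h, at the edge of the random range of 5 to 13, and for the G1/S genes and the SRF and YAP targets called at 8 h, with 6 of 24 at the edge of 6 to 15 and 6 of 14 at the edge of 6 to 12. The other 4 of the 9 lists compared at 8 h lay inside their ranges. Of the 48 G2/M genes called at 16 h, 20 were also called at 8 h, against 30 to 41 among matched random genes. Histone genes had 7 of 40 against 27 to 36, so for these lists the low numbers were not particular to 0 h. Cytoplasmic ribosomal protein genes were above their range at 8 h, with 66 of 66 against 48 to 59. The other lists lay inside theirs at 8 h. The calls of G2/M genes were not confined to 16 h. Of the 48 called at 16 h, 19 were also called at 20 h, against 6 to 16 among random genes of matched −log10 q. Histone genes, with 39 of 40 against 6 to 17, and cytoplasmic ribosomal protein genes, with 53 of 66 against 14 to 28, were above their ranges too. No list lay below its range at 20 h. A difference between stages of the cell cycle, which the design names, stays open and untested, since each stage has 1 library.

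Histone genes were called at 16 and 20 h. More peaks of any kind on chromosome 13 at 20 h are argued against as the whole cause. At 16 h 25.9% of its other protein-coding genes were called, against 27.5% of other genes elsewhere, and 31 of its 53 histone genes. Of the 10 histone genes on other chromosomes, 9 were called at 16 h and 8 at 20 h. For the rise from 16 to 20 h this explanation stays open. That rise lay on chromosome 13 alone, from 31 to 44 histone genes. There 15.2% of the other genes were called at 20 h, against 6.85% elsewhere. A few wide peaks counted for many clustered genes are argued against by the 35 separate peaks behind the 52 genes called at 20 h. Reads shared between near-identical histone copies were not tested. The stage of the cell cycle is a hypothesis that may account for these calls, and it remains open beside a possible batch of the 20 h library, though 40 of the genes were called at 16 h already.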
